A study of Drosophila melanogaster with 4 samples.

How the data were processed

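Chromatin from Kc167 cells was immunoprecipitated with a rabbit polyclonal antibody (catalogue ab5095) raised against the C-terminal repeat of RNA polymerase II phosphorylated at serine 2, and the recovered DNA was sequenced. Kc167 is a cell line derived from late embryos of the fruit fly Drosophila melanogaster; per the labels it is female. The series holds 4 samples, which are 2 ChIP libraries (replicates 1 and 2) and 2 libraries of input DNA. Per the labels' protocols, cells were fixed with formaldehyde and their chromatin was sheared by sonication before the precipitation. The replicate numbers come from the sample titles. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

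The authors deposited 3 sets of regions, one for each ChIP library and one for the series as a whole, which is called the combined set here. Each region has a chromosome sequence, a start, an end and a score, and each is named by the authors as a region of significant enrichment or of significant depletion. The enriched regions are called clusters. The score of each region is the authors' own value, as deposited. It is used here to describe, rank, filter or weight regions within a set, also by arm, and to compare the 2 replicate sets, which are of nearly equal length. Scores are positive for enriched and negative for depleted regions, but their scale is not given in the sources used here. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The cluster caller, its threshold, the way in which the input libraries entered the calling and the way in which the replicates were combined are not given in the sources used here. Coordinates are on FlyBase release 5, per the file headers, and all positions are counted from 1. The headers list 14 sequences with their lengths. They are the arms 2L, 2R, 3L, 3R and X (the large arms), chromosome 4, 6 scaffolds of mapped heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet), and the sequence collections U and Uextra.

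The input libraries had no file of their own here and entered no comparison. Read counts were not part of the files, so the sequencing depth behind each cluster is unknown, and no value below carries a counting error from reads. The gene table at hand describes release 6 of the genome. Its positions could not be used with release 5 coordinates, so regions are given by position without gene names. The planned comparisons with annotated features, genes, gene lists and positions along genes were not run for this reason.

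Covered sequence was the summed width of clusters, and the covered share was that sum as a percentage of the sequence length in the headers. Overlap of the replicate sets was measured as the Jaccard index (shared bases over bases in either set) and as the share of clusters that overlap the other set by at least 1 bp, over at least 50% of the cluster, or by at least 50% of both clusters. Each overlap was compared with 1000 random circular shifts of the replicate 2 set within every sequence (100 for the reciprocal overlap), one-sided; the smallest p that 1000 shifts can give is 0.001. Such a p asks whether the 2 lists lie at the same places and does not compare conditions. Scores were compared across clusters that overlap one to one, with Pearson's r and Spearman's rho and 100000 permutations, two-sided. Clusters within a genome are not independent replicates. Values per replicate are given as mean ± SD with n = 2. Differences between arms were set beside this SD and not tested, since an exact sign-flip test over 2 replicates cannot give a two-sided p below 0.5. Intervals on shares of clusters are 95% exact (Clopper-Pearson) intervals and treat clusters as independent. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

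The overlap functions were tested on simulated data before use. In 3 simulated pairs of sets, with 5207 clusters in the first set of each, the planted overlap was recovered exactly in 3 pairs. The simulated clusters lay on a longer genome and were either identical in both sets or apart. Partial overlaps and split clusters were therefore not covered by this test.

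The design, the alternatives and the rule for the regions named in the text were fixed before the data were examined. The parts of the rule that need genes were not used. The others take the 5 clusters of the combined set with the highest score and the 5 widest among those that overlap clusters of both replicates, and the 3 highest-scoring clusters of each replicate that overlap none of the other. The alternatives were to merge clusters of a set less than 1 kb apart, to keep only the 6 main arms (the large arms and chromosome 4), to keep the better-scoring 50% of each set, to change the overlap that counts as shared, to leave out each replicate in turn, to use the combined set in place of the replicates, and to divide the score by the width.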

Results

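The genome-wide distribution of RNA polymerase II phosphorylated at serine 2 of its C-terminal repeat, the form that travels along transcribed genes during elongation, was profiled by ChIP-seq in Kc167 cells. There were 2 ChIP libraries and 2 input libraries; the inputs were not analysed here, and the depth of each library is unknown. Replicate 1 held 5207 clusters of enrichment over 22.1 Mb, and replicate 2 held 5190 clusters over 22.8 Mb. The mean was 5198.5 ± 12.0 clusters and 22.5 ± 0.47 Mb (SD, n = 2). The median cluster was 2860 bp wide in replicate 1 and 2924 bp in replicate 2, with a middle range from 2086 to 5025.5 bp in replicate 1 and from 2118 to 5225 bp in replicate 2. Clusters of 10 kb or more numbered 373 in replicate 1 and 414 in replicate 2. These long clusters held 24.6% and 26.6% of the covered sequence, respectively. The combined set listed 5566 clusters over 25.3 Mb, of which 529 were 10 kb or longer. Wider clusters had higher scores, with a Spearman correlation across clusters of 0.64 in replicate 1 and 0.63 in replicate 2.

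The first comparison asked whether both libraries placed the polymerase at the same sites. They did so for 21.3 Mb of sequence, which was 96.1% of the covered bases of replicate 1 and 93.4% of those of replicate 2. The Jaccard index was 0.90, against a mean of 0.10 and a maximum of 0.14 over 1000 circular shifts (one-sided permutation p = 0.001, the smallest the shifts can give). Of the replicate 1 clusters, 96.3% overlapped a cluster of replicate 2, against at most 36.1% after a shift (permutation p = 0.001). Of the replicate 2 clusters, 93.9% overlapped a cluster of replicate 1. The share of replicate 1 clusters was still 89.7% when at least 50% of both clusters had to overlap, against at most 7.89% in 100 shifts (permutation p = 0.0099, the smallest that 100 shifts can give). That left 193 clusters found in replicate 1 alone and 315 in replicate 2 alone.

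Along the arms, windows dense in clusters alternated with windows holding almost none, and both replicates traced the same profile.

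**Figure D1:**
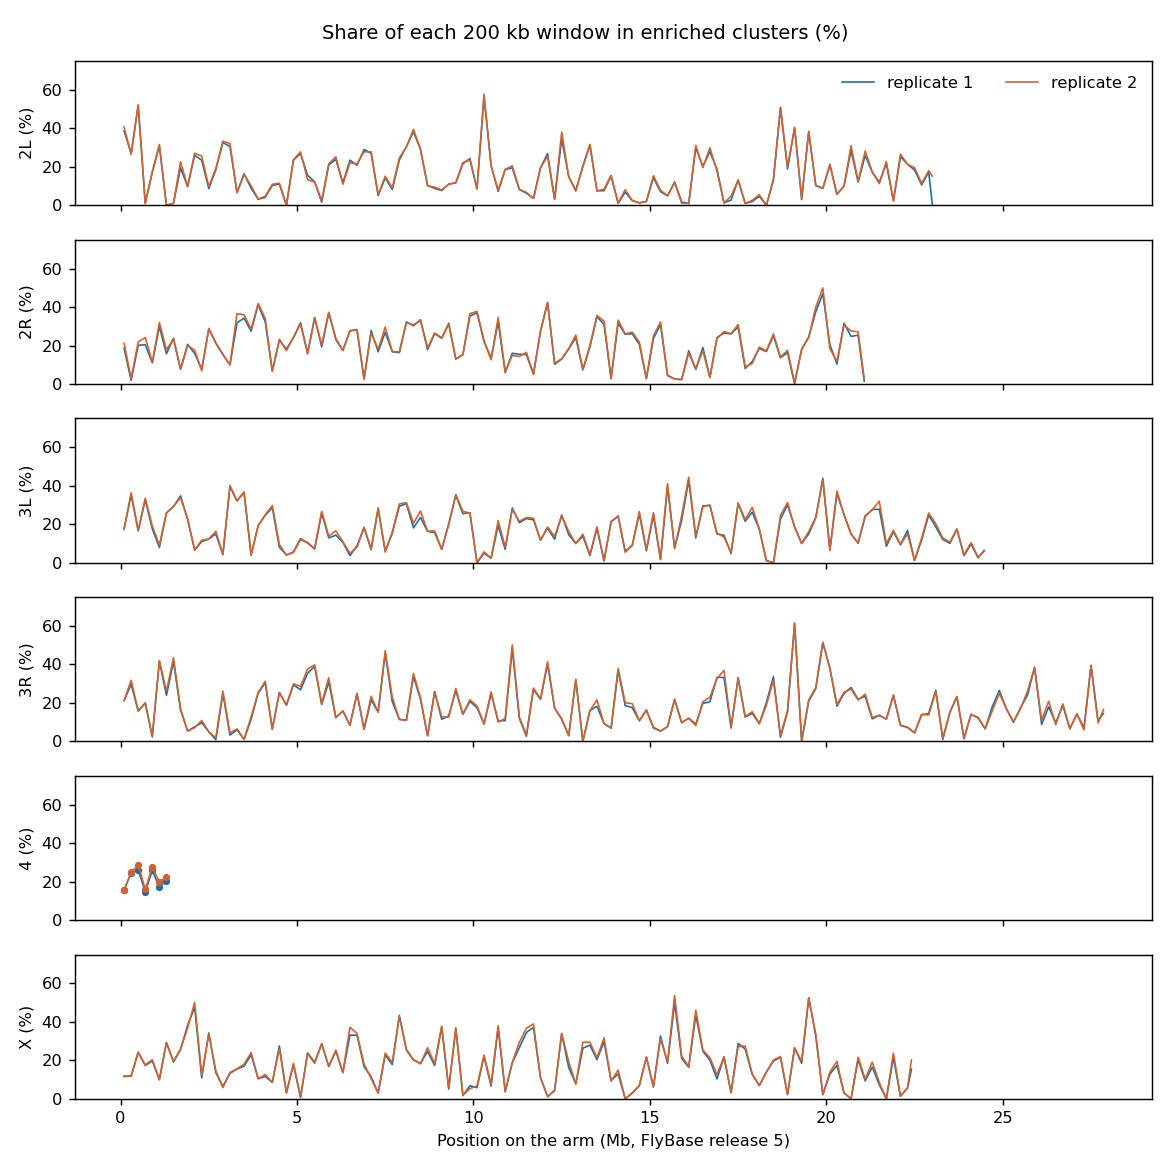
Share of each 200 kb window covered by enriched clusters (y axis, percent) along the arms 2L, 2R, 3L, 3R, 4 and X (x axis, position in Mb on FlyBase release 5), for replicate 1 (blue) and replicate 2 (orange). The 2 lines run close together along all 6 arms; over the whole genome the sets have a Jaccard index of 0.90.

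The replicates also ranked the clusters alike. Across the 4316 clusters that matched one to one, which were 82.9% of the replicate 1 clusters, the authors' scores had a Pearson r of 0.98 and a Spearman rho of 0.98 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Matched scores differed by a median of 0.08, and the SD of the difference was 0.14, whereas the matched scores ran up to 4.38 in replicate 1 and 4.37 in replicate 2. The largest difference between matched clusters was 1.73. Genomic clusters are not independent replicates, so these correlations describe the 2 lists and not a population of cultures.

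**Figure D2:**
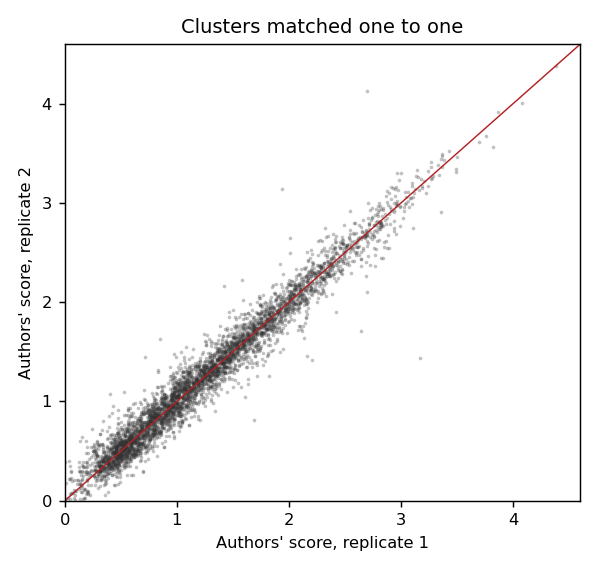
Authors' score of each of the 4316 clusters matched one to one in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units, whose scale is not given; the red line marks equal scores. The points lie along the line, with a Pearson r of 0.98.

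Among clusters of the combined set that overlapped both replicates, the 5 highest-scoring were close to the set's median width of 2849.5 bp. Combined clusters that did not overlap both replicates scored up to 3.92 and are not ranked here. The highest score in the combined set among clusters of both replicates belonged to X from 2210437 to 2212846, a cluster of 2410 bp with a combined score of 4.37 and replicate scores of 4.38 and 4.37. The second was on 2R from 19553249 to 19556446, 3198 bp wide, with a combined score of 3.93 and replicate scores of 4.08 and 4.01. A cluster on 3R from 8302037 to 8304466 followed with a combined score of 3.90 and replicate scores of 3.87 and 3.91. The next one, also on 3R, ran from 13768450 to 13771014 with a combined score of 3.72 and replicate scores of 3.76 and 3.68. The fifth lay on 3L from 1585423 to 1587835 and had a combined score of 3.65, with 3.70 in replicate 1 and 3.61 in replicate 2. All 5 were between 2410 and 3198 bp wide, and each was a single cluster in both replicates.

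The widest domains had scores between 1.26 and 1.70, above the combined median of 0.98. The widest ran on 3R from 1088814 to 1135046, a span of 46233 bp with a combined score of 1.56, of which replicate 1 covered 99.2% in 2 pieces and replicate 2 covered 99.9% in 1 piece. On X, a cluster of 43381 bp from 9443999 to 9487379 had a combined score of 1.70 and was a single cluster in both replicates. A second domain on X, from 16308446 to 16348960, measured 40515 bp with a combined score of 1.52; replicate 1 listed it in 4 pieces that covered 98.1% of it, and replicate 2 as 1 cluster over 99.9%. On 2R, the domain from 3842183 to 3879364 was 37182 bp wide and had a combined score of 1.26, and each replicate listed it in 2 pieces. The other 2R domain, from 4008273 to 4045123, was 36851 bp wide with a combined score of 1.55, and appeared as 3 pieces over 95.4% of its length in replicate 1 and as 1 cluster in replicate 2. The number of pieces in a domain varied more between the libraries than the sequence covered.

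The clusters that had no counterpart in the other replicate included a few with high scores. Of the 6 highest, 3 from each replicate, 4 lay on U, the collection of sequence that release 5 does not place on a chromosome. In replicate 1 the 3 highest were U from 1490619 to 1492342 with a score of 3.22, 3R from 13334998 to 13336326 with a score of 2.30, and U from 9759186 to 9761040 with a score of 2.25. In replicate 2 they were U from 4924807 to 4926190 with a score of 4.46, which was the highest of that set, U from 6936770 to 6938416 with a score of 3.76, and 2L from 23006892 to 23008641 with a score of 3.55. All 6 overlapped a cluster of the combined set. Unmatched clusters were narrower than matched ones, with a median width of 1555 against 2956 bp in replicate 1 and 1620 against 3103 bp in replicate 2.

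Chromosome arms were then compared by the share of their sequence in clusters. Among the large arms, 2R had the highest share, 20.9% ± 0.38 (SD, n = 2), and 2L the lowest, 16.1% ± 0.29. The arms 3L, 3R and X stood between them at 17.5% ± 0.39, 18.3% ± 0.31 and 18.5% ± 0.42, respectively. Replicate 2 had a slightly higher share than replicate 1 on each of the 5 large arms, and the gap between 2R and 2L was larger than the spread between replicates. X exceeded the pooled autosomal large arms by 0.38 ± 0.08 percentage points (n = 2), with 0.32 in replicate 1 and 0.43 in replicate 2. That difference was small beside the SD of 1.99 percentage points across the 4 autosomal arms in replicate 1 and 2.03 in replicate 2. Both X values therefore lay within the range of the autosomal arms, which was 15.9% to 20.6% in replicate 1 and 16.3% to 21.1% in replicate 2.

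Chromosome 4, the small chromosome in which genes are interspersed with heterochromatin, had more clusters for its length than the large arms, and their scores were lower. It carried 61.4 ± 1.05 clusters per Mb against 41.5 ± 0.20 on the large arms (SD, n = 2). The covered share of chromosome 4 was 21.4% ± 1.08, which exceeded that of the pooled large arms by 3.15 ± 0.72 percentage points (2.64 in replicate 1 and 3.66 in replicate 2). In the combined set the excess over the pooled large arms was 6.66 percentage points. The arm 2R came closer, with 20.60% in replicate 1 and 21.14% in replicate 2, against 20.59% and 22.11% on chromosome 4. In the combined set 2R stood at 23.4% and chromosome 4 at 27.0%. The median score was 0.91 in replicate 1 and 0.95 in replicate 2 on chromosome 4, against 1.10 and 1.12 on the large arms. When only the better-scoring 50% of each set was kept, the covered share was 12.3% on chromosome 4 and 12.5% on the large arms, so the sign of the difference turned.

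The heterochromatic scaffolds held far fewer clusters. Together they had 12.7 ± 0.23 clusters per Mb and a covered share of 4.33% ± 0.10 (SD, n = 2), a difference of -13.9 ± 0.26 percentage points from the large arms. These values are over the full sequence length in the headers. On how much of it reads could be placed is unknown, so a lower share need not mean less polymerase. The scaffolds were unequal. The shares were 8.82% ± 1.09 on XHet, 8.19% ± 0.45 on 3LHet, 5.89% ± 0.38 on 2LHet, 3.04% ± 0.10 on 2RHet, 2.15% ± 0.83 on YHet and 1.80% ± 0.10 on 3RHet. XHet and YHet rest on few clusters, 4 and 6 on XHet and 2 and 4 on YHet in replicates 1 and 2. U was covered over 1.19% ± 0.15 of its length by 49 and 60 clusters, and their median score of 1.59 in each replicate was higher than that of the large arms. In the combined set the covered share was 2.10% on U and 4.24% on YHet. No set listed a cluster on Uextra; whether that sequence was searched is not given in the sources used here.

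**Figure D3:**
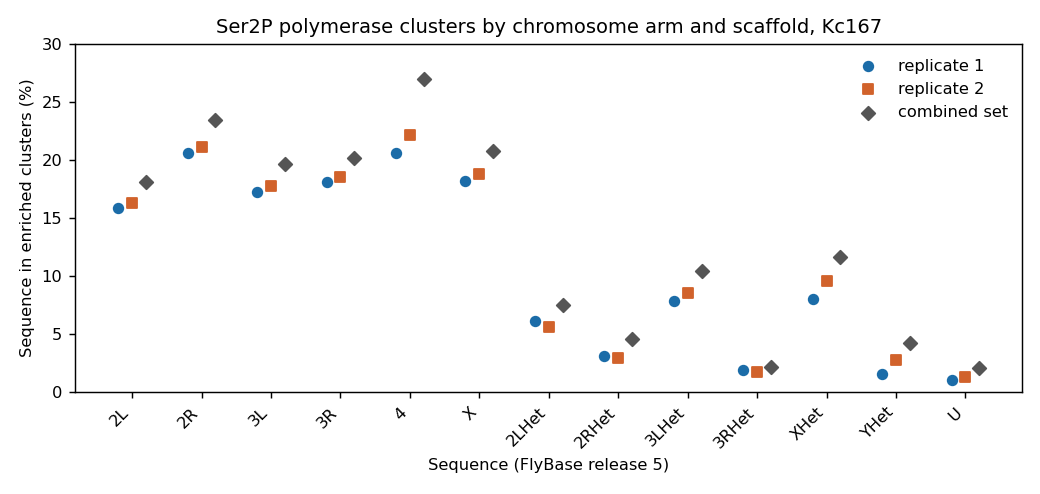
Share of each chromosome arm, heterochromatic scaffold and U in enriched clusters (y axis, percent of the sequence length in the headers), with one point each for replicate 1, replicate 2 and the combined set. The large arms and chromosome 4 lie between 15.9% and 22.1% in the replicates, where the scaffolds and U lie below 10%; chromosome 4 stands highest in the combined set at 27.0%.

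The combined set was compared with the replicates to see what it added. It contained almost all of what they shared, 99.9% of the bases in both replicates, and 99.7% and 99.5% of the covered bases of replicates 1 and 2. Of its 5566 clusters, 4497 overlapped both replicates (80.8%, 95% exact interval 79.7 to 81.8), 420 overlapped one, and 649 overlapped neither (11.7%, 10.8 to 12.5). By sequence, 83.9% of the combined bases lay in both replicates, 8.85% in one and 7.26% in neither. Clusters that overlapped both replicates had a median width of 3538 bp and a median score of 1.15. Clusters that overlapped one replicate had a median width of 1785.5 bp and a median score of 0.33. Clusters in neither had a median width of 1270 bp and a median score of 0.38, and the highest of them scored 3.84. The smallest combined cluster measured 1001 bp, against 1301 and 1303 bp in the replicates.

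The gain was unequal across the genome. The combined set held 1.05 times the mean replicate number of clusters on the large arms, 1.28 times on chromosome 4, 1.45 times on the heterochromatic scaffolds and 1.87 times on U. On the scaffolds and U together, 81 of 272 combined clusters overlapped neither replicate (29.8%, 95% exact interval 24.4 to 35.6), against 546 of 5188 on the large arms (10.5%, 9.70 to 11.4). On chromosome 4 the number was 22 of 106.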

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

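The tests on depleted regions, the test on the smallest cluster width and the bootstrap intervals were chosen only after the result was seen.

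Besides clusters of enrichment, the authors listed regions of significant depletion, which enter no comparison above: 8 in replicate 1, 14 in replicate 2 and 74 in the combined set. These regions lie outside the main measurement. Of the 74, 21 lay on 3R, 16 on 3L, 13 on X, 12 on 2R, 11 on 2L and 1 on 3LHet. Their widths ran from 1293 to 1908 bp, and their scores lay between -0.26 and -0.00082. The sign of these calls was not stable between sets: 49 of the 74 overlapped a cluster that at least one replicate listed as enriched, 16 of them in both replicates, and 15 overlapped a depleted region of a replicate. A further 16 overlapped no region of either replicate. All of the enriched clusters hit, 27 in replicate 1 and 38 in replicate 2, were among the weakest 10% of their replicate by score (100% in both). A sign set by a score near 0 stays open, because the combined scores of these regions were themselves near 0 and left little room for another outcome. Noise in the sign between the libraries stays open as well: all 8 depleted regions of replicate 1 overlapped a region of replicate 2, which was listed as depleted for 3 and as enriched for 5. In 1000 circular shifts no depleted region was shared (one-sided permutation p = 0.001, the smallest they can give), but shifts test the position, which these regions shared whatever their sign. The 3 lie on 3L from 2151014 to 2152671, on 3R from 22783416 to 22785069 and on 3R from 27770989 to 27772492. A fixed calling window as the source of the narrow widths stays open. Of equally weak enriched clusters of the combined set, 71.5% fell in the width range of its depleted regions, against 12.2% of all its enriched clusters. The shares were 85.0% of 20 weak clusters against 7.97% of all in replicate 1, and 63.5% of 52 against 5.65% in replicate 2. Weak clusters were narrower in general, so these shares do not decide the question. The design offers no group on which a biological explanation of these regions could be tested.

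A second pattern is the larger gain of the combined set on the heterochromatic scaffolds and U, where 29.8% of combined clusters overlapped neither replicate against 10.5% on the large arms. Weak scores are argued against only for the pool of scaffolds and U. Large-arm clusters weighted to the scores of that pool would miss 9.24%, which is 20.5 percentage points lower (95% bootstrap interval 14.9 to 26.6). The median combined score was 1.09 in the pool and 0.98 on the large arms. The pool mixed heterochromatic scaffolds, with a median of 0.80, and U, with a median of 1.54. Weak scores on the scaffolds without U were not tested and stay open. Narrow clusters may account for much of the difference. Weighting to the scaffold widths in bins of 500 bp gave 24.1%, which is 5.68 points below the observed share (interval 2.35 to 9.28). Whether width accounts for all of it cannot be told from these bins. The smallest replicate cluster, 1301 bp, falls inside a bin, and 353 of the 369 combined clusters narrower than that overlapped neither replicate. The smaller minimum width of the combined set goes with many of the missed clusters, as 54.4% of all 649 were narrower than 1301 bp. It is argued against as the sole source of the difference. Among clusters of 1301 bp or more the missed share was still 17.0% (95% exact interval 12.3 to 22.4) on the scaffolds and U against 5.13% (4.52 to 5.78) on the large arms. Sparse placement of reads in repeated sequence, and a real difference between heterochromatin and the arms, both stay open and were not tested, because the files hold no read depth and no sequence.

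Another pattern is the set of clusters found in one replicate alone. Most of them had weak scores: 77.2% of those of replicate 1 and 81.3% of those of replicate 2 were in the lowest 25% of their set by score. Most clusters in that lowest 25% were matched all the same. The unmatched made up 11.4% of it in replicate 1 and 19.7% in replicate 2, against 2.15% and 2.08% of the next 25%. Whether they lay near the limit of calling cannot be told, as the caller's threshold is not given. Pieces cut off from a shared cluster are argued against as the main source, since 32.1% of those in replicate 1 and 26.0% in replicate 2 lay within 1 kb of a cluster of the other replicate. The 16 unmatched clusters of replicate 1 and 32 of replicate 2 that scored above the median of their set are not accounted for by a weak score. Unmatched clusters made up 12.1% and 19.0% of the clusters on the scaffolds and U, and 3.39% and 5.52% of those on the large arms, in replicates 1 and 2, respectively.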

How the results depend on the processing

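Each alternative here was planned, and no test was chosen after the result was seen. The agreement of the replicates stayed above every circular shift under each alternative, with a Jaccard index of 0.91 after merging, 0.90 on the main arms and 0.86 for the better-scoring 50%. Merging lowered the number of clusters from 5207 to 4271 in replicate 1 and from 5190 to 4314 in replicate 2, so that replicate 2 then had more. The share of replicate 1 clusters that matched stayed between 89.7% and 96.9%, and Spearman's rho of the scores was 0.98 with 50% reciprocal overlap and 0.93 after division by width. On the main arms alone, replicates 1 and 2 covered 21.6 and 22.3 Mb. The better-scoring 50% held 2604 and 2595 clusters over 15.1 and 15.5 Mb, by the construction of that filter. Of the better-scoring 50% of the combined clusters, 83.6% overlapped clusters kept in both replicates. The score limit of the filter was 0.98 in the combined set and 1.10 and 1.12 in replicates 1 and 2. This share is therefore not directly comparable with that of all combined clusters. The excess of chromosome 4 over the large arms was 6.66 percentage points in the combined set and reversed to -0.12 with the better-scoring 50%; the lower scores on chromosome 4 remove more of its clusters at that limit. The excess of X was 0.48 points in the combined set, and the heterochromatic scaffolds stood at -14.6 points from the large arms in the combined set and at -10.0 with the better-scoring 50%. For the shifts in the combined set the cause was not tested. Leaving out either replicate changed no sign of these 3 differences. For single arms, scaffolds and U, 25 of 26 values from the combined set or the better-scoring 50% moved by more than the spread between replicates. The exception was YHet with the better-scoring 50%. The direction of these moves was largely set by construction. Keeping the better-scoring 50% can only lower a share, and the combined set held 99.7% and 99.5% of the covered bases of replicates 1 and 2. No paired analysis was possible because the input libraries that share the replicate numbers have no values here. The alternatives for annotated features, genes, gene lists and positions along genes were not run, as no annotation of release 5 was used. Read depth is unknown, so what it limits could not be measured.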

Other observations

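No test here was chosen after its result was seen, but the listing of the highest scores by arm was not planned.

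The highest scores were spread unevenly over the arms. X carried 18.6% of the clusters in each replicate, but 30 of the 261 clusters in the top 5% by score in replicate 1 (11.5%) and 35 of 260 in replicate 2 (13.5%). Arm 3R carried 20.8% and 20.6% of the clusters and 25.3% and 24.2% of the top 5%. U carried 0.94% and 1.16% of the clusters and 3.07% and 3.46% of the top 5%, 8 and 9 clusters. Chromosome 4, with 1.57% and 1.62% of the clusters, had 1 cluster in the top 5% of each replicate, but 4 of 279 in the combined set (1.43%, against 1.90% of all its clusters). Although the cell line is female per the labels, YHet, which holds sequence assigned to the Y chromosome, had 2 clusters in replicate 1, 4 in replicate 2 and 8 in the combined set. The source of these YHet clusters was not tested, and they are counted among those of the heterochromatic scaffolds.

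Clusters on the large arms were grouped, leaving long stretches without any. Outside the clusters of both replicates there were 196 gaps of 100 kb or more, which together held 30.9 Mb or 25.9% of the large arms. Placing the same clusters at random left 3.23% on average and at most 4.86% in 1000 placements (one-sided permutation p = 0.001, the smallest they can give), which argues against random spacing. The share was highest on 2L at 31.9% and lowest on 2R at 18.7%. The longest gap ran on 3L from 18228518 to 18609247, 381 kb, and held 2 clusters of the combined set; the next, on X from 20533717 to 20898029, was 364 kb long and held none, and neither did the third, on 2L from 4478131 to 4828940, of 351 kb. The longest gap in any of the 1000 placements was 387 kb. How often a placement held a gap this long was not counted, so the length of single gaps is not judged here. In all, 45 of the 196 gaps held at least 1 cluster of the combined set. Gene-poor or silent domains and stretches where few reads can be placed were not told apart, as neither genes nor read depth were used here.

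Whether coverage falls towards the centromere on every large arm was examined on the proximal 1 Mb of each, and the sign of the difference was not the same on all. Coverage of the proximal 1 Mb was lower than that of the rest of the arm in both replicates on 4 of the 5 arms. The difference in replicates 1 and 2 was -11.2 and -11.2 percentage points on X, -8.52 and -8.92 on 3L, -6.49 and -5.05 on 2R, and only -0.28 and -0.24 on 3R, where the combined set had a difference of 0.68 in the opposite direction. On 2L the proximal 1 Mb was more covered than the rest, by 2.83 and 3.41 points. Each proximal 1 Mb was compared with the whole rest of its arm and not with other stretches of 1 Mb. Coverage varied widely along the arms, and whether these differences exceed that variation was not tested.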
